A study of Mus musculus with 6 samples.

How the data were processed

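Small RNA was sequenced from pancreatic islets of mice on the diets labelled HFD and NCD, with 3 libraries per diet. Per the labels' protocols, total RNA was isolated on silica columns (RNeasy mini kit), RNA integrity was checked on a Bioanalyzer, and libraries were made with the NEBNext small RNA kit for Illumina sequencing. Columns of this kind, run with a total RNA protocol, retain short RNA incompletely, and ligation-based small RNA libraries favour some miRNA ends over others. Levels of different miRNAs within a library are therefore less comparable than levels of 1 miRNA between libraries. The aligner, the counting tool, the genome build and the miRNA annotation release are not given in the sources used here.

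The deposited table holds a raw read count per mature miRNA and library, per the file headers. It lists 1011 rows, of which 958 carry mouse miRNA names and 53 are predicted miRNAs with a number only. The predicted rows took at most 0.0117% of a library's reads. The authors' deposited TPM values were found to equal CPM on each library's raw total, to within a relative difference of 4.61e-09, so they hold no length term and no further normalisation. Counting was by name, without a stated strand setting. There were 39 pairs of rows whose sequences are reverse complements over at least 18 bases. Of the 25 pairs with at least 100 reads in the higher row, 12 had totals within 5% of each other. The rows for miR-122-5p and miR-122b-3p held the same 8120 reads, and those for miR-24-3p and miR-3074-5p held 92010 and 91969. Such pairs appear to hold the same reads under both names and are not separate measurements. Near-identical miRNAs, such as miR-146a-5p and miR-146b-5p, miR-7a-5p and miR-7b-5p, or miR-27a-3p and miR-27b-3p, can also exchange reads, and how shared reads were counted is not given in the sources used here.

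Library totals ran from 7166712 to 11172255 counts. A count of 0 allowed a level of up to 0.213 to 0.445 CPM, taken as 3 counts of the total scaled by the TMM factor. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. Libraries of 1 diet differed well beyond sampling noise, with chi-square values of 378 to 1894 per degree of freedom, so none appeared to be 1 library deposited under 2 names. Repeat preparations of 1 RNA would also differ in this way. The labels do not say whether the libraries came from separate animals or pools, and p-values measure the spread between these samples.

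The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr with its minimum count of 10, TMM factors, estimateDisp and the quasi-likelihood fit and test (glmQLFit, glmQLFTest) with diet as the only term. Fold changes are HFD against NCD. Standard errors are on the log2 scale, p-values were adjusted by the Benjamini-Hochberg method over the 406 miRNAs tested, and the threshold was an adjusted p of 0.05. Levels are CPM values, on library totals scaled by the TMM factors, as mean ± SD. For tested miRNAs the totals leave out the rows removed by the filter, which held at most 0.0351% of a library's reads. Shares of reads are percentages of the raw library total.

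In all, 28 miRNA lists were fixed before the data were examined. They cover cell type markers, genomic clusters, seed families, and miRNAs altered in obese or diabetic islets or induced by inflammation and stress. The 26 lists with at least 3 tested members were tested with camera (limma 3.58.1) on voom log2 values with a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The 5p to 3p ratio of miR-27a was compared with a two-sided exact permutation test of the log2 ratio with a prior count of 0.5 per arm.

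The miRNAs named in the text were chosen by a rule fixed in advance. It took up to 12 miRNAs with the largest rise and up to 12 with the largest fall among those with adjusted p under 0.05, a mean of at least 10 CPM and no overlap between diets. Where fewer than 5 passed in a direction, the smallest p values filled it to 5 and are described as not having passed. The rule also took the mir-23a/27a/24-2 and mir-23b/27b/24-1 clusters, the 10 most abundant miRNAs and up to 4 of the most abundant tested members of each list. Exceptions are stated where they occur.

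Alternatives chosen in advance were other size factors (RLE, upper quartile, library totals only), no filter or a mean of at least 100 counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), robust and legacy quasi-likelihood settings, the replicate number as a block, the most abundant miRNA left out, each library left out, and an adjusted p of 0.1. Keeping 1 row of each reverse-complementary pair, removing a linear GC trend per library (also with the block), and leaving out miR-146a-5p from the list tests were added after the data were seen.

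The steps were tested on simulated data: in 10 runs with counts drawn for the 406 miRNAs from the real means, library sizes and dispersions, 200 miRNAs were changed. At a 6-fold change 98.3% were recovered and at a 2-fold change 34.9%, and 2.89% of calls were false. Counts were drawn independently for each miRNA, so the simulation does not show how often the list test calls lists whose members are correlated. With fewer changed miRNAs the adjustment is stricter and the shares recovered would be lower.

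Hairpin positions came from exact matches of the mature sequences in the table to miRNA transcripts of GENCODE M21 on GRCm38, which may not be the build used for counting. Positions were looked up for 41 of the miRNAs named in the text. Of these 40 had a match, and 8 of the 40 matched more than 1 hairpin. Enclosing genes are those of the same annotation.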

Results

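Mature miRNAs were counted in pancreatic islets, the clusters of hormone-secreting cells of the pancreas, from mice on the HFD or the NCD diet, with 3 libraries per diet. The HFD libraries held 10678638, 9431818 and 11059628 counts for replicates 1, 2 and 3. The NCD libraries held 7166712, 11172255 and 8121430. Of 1011 listed miRNAs, 406 passed the filter on low counts.

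A few miRNAs filled most of each library in both diets. The 10 most abundant miRNAs took 84.1% to 89.9% of the reads and the first 3 took 71.0% to 79.0%. By the mean over all 6 libraries the most abundant was miR-375-3p, the islet-enriched miRNA that restrains insulin secretion, with 29.3% ± 5.93 of reads in HFD and 35.6% ± 7.35 in NCD islets (SD, n = 3 each). miR-148a-3p had 31.7% ± 3.63 and 26.2% ± 3.27, so that its mean share lay above that of miR-375-3p in HFD and below it in NCD islets. miR-7a-5p, a brake on beta-cell proliferation, had 14.9% ± 5.43 and 13.9% ± 1.52. The others were miR-7b-5p, miR-21a-5p, let-7f-5p, miR-99b-5p, miR-200b-3p, miR-200a-3p and miR-26a-5p. None of these 10 passed the edgeR test between diets. The mature miR-375-3p (UUUGUUCGUUCGGCUCGCGUGA) matches a hairpin on chromosome 1 from 74900658 to 74900721 (GRCm38, minus strand), outside any other annotated gene. The miR-148a-3p hairpin lies on chromosome 6 from 51269812 to 51269910, also outside other genes.

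The libraries were not alike within a diet. The TMM factor of NCD 3 was 1.73, while the other 5 factors lay between 0.84 and 0.995. In NCD 3, 53 of the tested miRNAs were at least doubled and 45 at least halved against the mean of the other 5 libraries on the log2 scale. The acinar-enriched miR-217-5p and miR-216b-5p were highest in NCD 3, with 315 and 96.2 CPM, and lowest in HFD 1, with 18.04 and 2.12 CPM. NCD 1 held 757 CPM of the liver miRNA miR-122-5p, against 34.1 to 78.6 CPM in the other libraries.

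The first comparison asked which miRNAs differ between HFD and NCD islets. The 1 miRNA that passed the threshold was miR-146a-5p, an NF-kB-induced miRNA that dampens inflammatory signalling, which was 5.28-fold higher in HFD islets. Its level was 4049 ± 1262 CPM in HFD and 767 ± 188 CPM in NCD islets (SD, n = 3 each), and each HFD library lay above each NCD library. The log2 fold change was 2.40 with a standard error of 0.35 and an adjusted p of 0.00369 (edgeR quasi-likelihood test). The mature miRNA (UGAGAACUGAAUUCCAUGGGUU) matches a hairpin on chromosome 11 from 43374397 to 43374461 (minus strand), outside any other annotated gene. The near-identical miR-146b-5p, encoded on chromosome 19 from 46342762 to 46342870 in an intron of Mfsd13a, had a log2 fold change of 0.68 ± 0.34 (SE) and did not pass (edgeR adjusted p = 0.505).

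With edgeR, 1 miRNA was higher and 0 were lower in HFD islets, and 41 miRNAs had an unadjusted p under 0.05, 20 of them higher and 21 lower, where 20.3 would be reached by chance. DESeq2 called 3 higher and 0 lower, and limma-voom 1 and 0. The diets did not overlap for 62 miRNAs, or 15.3% of those tested, where chance gives 10%. The call of miR-146a-5p ended without NCD 1 (adjusted p = 0.0724 by edgeR), with library totals as the only scaling (0.188), and with limma-trend on log2(TPM + 1) (0.0874) or log2(TPM + 0.1) (0.0913), while its log2 fold change stayed at 2.03 or more under every alternative and its adjusted p ranged from 5.7e-08 to 0.188. The count rose to 8 without a filter (3 higher and 5 lower), to 4 without NCD 2 (1 and 3) and to 3 without NCD 3 (1 and 2), where each lower count holds the shared reads of miR-122-5p and miR-122b-3p under both names. Library totals moved the median log2 fold change of all miRNAs from 0.02 to -0.37.

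**Figure D1:**
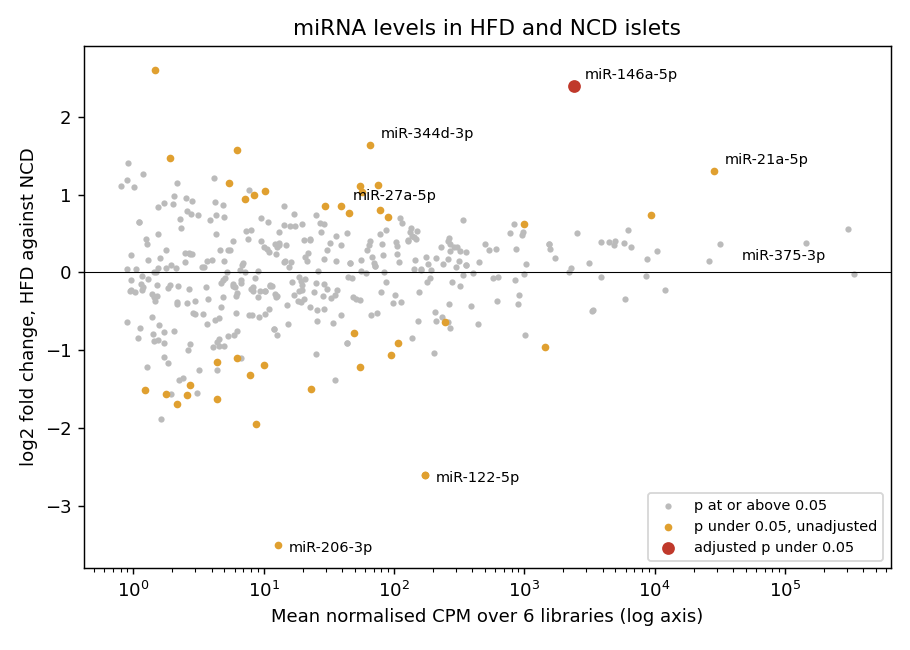
Each point is 1 of the 406 tested miRNAs, with its mean normalised CPM over the 6 libraries on a log axis and its log2 fold change in HFD against NCD islets. The single red point, miR-146a-5p at 2.40, passed an adjusted p of 0.05, and orange points had only an unadjusted p under 0.05.

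The next miRNAs by p on the higher side did not pass with edgeR. miR-344d-3p had 99.4 ± 36.1 CPM in HFD and 32.3 ± 8.51 CPM in NCD islets. miR-21a-5p, an abundant miRNA induced in stress and inflammation, had 40390 ± 10516 and 16424 ± 2658 CPM. Their log2 fold changes were 1.63 ± 0.38 and 1.30 ± 0.32 (SE), both with an edgeR adjusted p of 0.184. Both were called by DESeq2, with an adjusted p of 0.0266 each, and by edgeR without the filter, with 0.0234 for miR-344d-3p and 0.0178 for miR-21a-5p, while over all alternatives the values reached 0.528 and 0.601. The hairpin of miR-21a-5p lies on chromosome 11 from 86584067 to 86584158 (minus strand) within Vmp1, overlapping an annotated exon, and miR-344d-3p matches 5 hairpins on chromosome 7. miR-212-5p and miR-132-5p, neighbours on chromosome 11 in an intron of 1700016P03Rik, had log2 fold changes of 1.12 ± 0.37 and 1.13 ± 0.39. The edgeR adjusted p was 0.363 each, and without HFD 3 the log2 fold change of miR-132-5p was 0.65. The 3p arms had smaller log2 fold changes, 0.85 for miR-212-3p, named here outside the rule, and 0.51 for miR-132-3p (edgeR adjusted p = 0.586 and 0.684).

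On the lower side none passed. The miR-122-5p row, whose reads are repeated under miR-122b-3p, had 48.9 ± 17.5 CPM in HFD and 299 ± 397 CPM in NCD islets, a log2 fold change of -2.61 ± 0.77 (edgeR adjusted p = 0.277). The muscle miRNA miR-206-3p had 2.08 ± 1.49 and 23.9 ± 31.1 CPM, a log2 fold change of -3.50 ± 1.03 (adjusted p = 0.277). Both NCD means rested on NCD 1: without it the log2 fold changes were -0.59 ± 0.40 and -1.79 ± 0.83. Both passed with edgeR without NCD 2, with adjusted p of 0.00574 and 0.0033, and without the filter on low counts, with 3.49e-08 and 1.38e-08, and miR-122-5p also passed without NCD 3 (0.0389). Over all alternatives the adjusted p of both reached 0.752. miR-125a-5p had 977 ± 217.2 CPM in HFD and 1900 ± 454 CPM in NCD islets, a log2 fold change of -0.96 ± 0.32. miR-328-3p had 33.3 ± 4.82 and 77.0 ± 40.6 CPM, a log2 fold change of -1.21 ± 0.41 that was -0.76 without NCD 3, and its adjusted p was 0.363, as was that of miR-125a-5p.

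**Figure D2:**
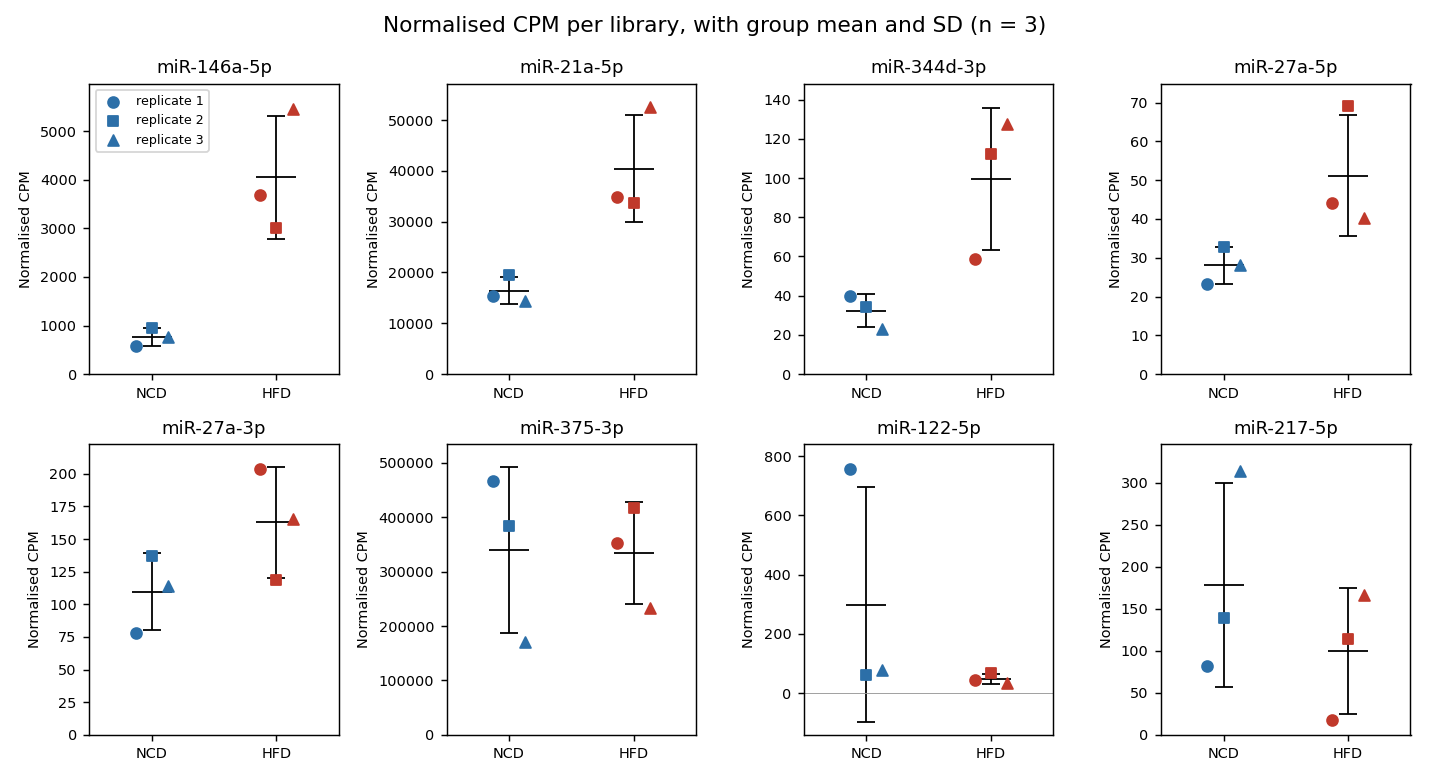
Normalised CPM of 8 miRNAs in each library, with blue points for NCD and red for HFD, marker shapes for the replicate number, and the mean and SD of each diet in black (n = 3). The diets do not overlap for miR-146a-5p, miR-21a-5p, miR-344d-3p and miR-27a-5p, while the NCD mean of miR-122-5p is set by NCD 1 at 757 CPM.

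The series concerns miR-27a-5p carried by vesicles from visceral fat cells, so the second comparison asked for its level in the islets. miR-27a-5p was at 51.1 ± 15.6 CPM in HFD and 28.1 ± 4.75 CPM in NCD islets (SD, n = 3 each), with 40.2 to 69.0 CPM in the HFD and 23.3 to 32.8 CPM in the NCD libraries. The log2 fold change was 0.85 with a standard error of 0.35. The unadjusted p was 0.0312 in the edgeR quasi-likelihood test, and the adjusted p over all miRNAs was 0.48, so it did not pass. The mature miRNA (AGGGCUUAGCUGCUUGUGAGCA) matches a hairpin on chromosome 8 from 84208672 to 84208758 (plus strand), outside any other annotated gene, between those of miR-23a and miR-24-2. With library totals only the log2 fold change was 0.44 and the unadjusted p 0.356, and without HFD 2, the library with the highest level, it was 0.54.

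The other products of this cluster did not pass either. miR-27a-3p, the more abundant arm, had 163 ± 42.8 CPM in HFD and 110 ± 29.7 CPM in NCD islets, a log2 fold change of 0.57 ± 0.34 (SE) that was 0.34 without HFD 1 and 0.31 without NCD 1. miR-24-3p, which matches both clusters and shares its reads with miR-3074-5p, had a value of 0.36 ± 0.29, which became -0.07 with library totals only and 0.17 without NCD 1. miR-24-2-5p had 0.42 ± 0.36, which was 0.22 without HFD 3 and 0.24 without NCD 1, and miR-23a-3p had -0.06 ± 0.32, the latter turning to 0.06 without NCD 3. In the paralogous cluster on chromosome 13, miR-27b-3p was the most abundant product with 5693 ± 1486 and 4298 ± 1555 CPM. Its log2 fold change was 0.41 ± 0.34, that of miR-27b-5p 0.52 ± 0.34, that of miR-23b-3p -0.30 ± 0.31 and that of miR-23b-5p -0.96 ± 0.49, and the edgeR adjusted p of each was above that of miR-27a-5p. These values moved with single libraries: miR-27b-3p was at 0.15 without HFD 1, 0.19 without NCD 3 and 0.71 without NCD 2, and miR-23b-3p at -0.13 without NCD 3 and -0.52 without NCD 1. With library totals only, which lowered the median log2 fold change of all miRNAs to -0.37, miR-27a-3p was at 0.16, miR-24-2-5p at 0.046, miR-27b-3p at 0.11, miR-27b-5p at 0.16, miR-23a-3p at -0.50 and miR-23b-3p at -0.76. As lists, the mir-23a/27a/24-2 cluster had 4 of 5 tested members with a positive fold change and a camera adjusted p of 0.129 (0.671 with an estimated correlation). The mir-23b/27b/24-1 cluster had 5 of 7 and an adjusted p of 0.634. These 5 include miR-24-1-5p and miR-3074-1-3p, which appear to hold the same reads (642 and 622). They also include miR-3074-5p, whose reads are counted in the first list as miR-24-3p.

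The third comparison asked for the balance of the arms of miR-27a, which come from 1 hairpin. The 5p arm made up 17.8%, 36.8% and 19.5% of the miR-27a reads in HFD replicates 1, 2 and 3, and 23.0%, 19.3% and 19.8% in the NCD replicates. The miR-27a-3p sequence differs by 1 base from that of the far more abundant miR-27b-3p. How shared reads were counted is not given, so the 3p counts may hold miR-27b-3p reads, and the ratio may not be that of 1 hairpin. The mean log2 ratio of 5p to 3p was -1.68 ± 0.78 in HFD and -1.94 ± 0.17 in NCD islets (SD, n = 3 each). The difference of 0.26 was smaller than the spread between HFD libraries and gave p = 0.9 in a two-sided exact permutation test, where 3 against 3 cannot go below 0.1. It rested on HFD 2: without it the difference was -0.18.

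The fourth comparison asked whether groups of related miRNAs differ together. None of the 26 lists passed an adjusted p of 0.05 with camera. By unadjusted p, 8 were under 0.05, and 0 passed with an estimated correlation or by fry's test for a shared direction, while 4 passed fry's test for change in either direction. The lowest adjusted p, 0.0624, was that of the miR-148 and miR-152 family, with a positive fold change for 6 of 6 members and a median log2 fold change of 0.53. Its members include miR-148a-3p (0.56 ± 0.37, SE), miR-148b-3p (0.50 ± 0.38) and miR-152-3p (0.36 ± 0.30), of which the first 2 were 0.30 and 0.15 without NCD 3. This list passed under 10 of 18 alternatives, among them library totals only, no filter, the replicate block and leaving out HFD 1, HFD 2, NCD 2 or NCD 3, and its adjusted p was 0.671 with an estimated correlation.

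The list of inflammation and stress-induced miRNAs had 8 of 11 members with a positive fold change, a median of 0.35 and an adjusted p of 0.0688, which was 0.354 without miR-146a-5p. In this list 1 member was called over all miRNAs and 2, miR-146a-5p and miR-21a-5p, when adjusted over the list alone. The list of miRNAs altered in obese or diabetic islets had 17 of 25 positive, a median of 0.26 and an adjusted p of 0.0874 (0.272 without miR-146a-5p), with the same 2 members called when adjusted over the list alone. The 20 tested islet endocrine-enriched miRNAs had a median of 0.12 and an adjusted p of 0.821, and 0 were called when adjusted over the list alone.

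Among markers of other cells, the 3 acinar-enriched miRNAs (miR-217-5p, miR-216b-5p and miR-216a-3p) had negative fold changes, with a median of -0.85 and a camera adjusted p of 0.0688. The spread was wide, with HFD 1 lowest and NCD 3 highest in each, and without NCD 3 the log2 fold change of miR-217-5p was -0.15. The endothelial-enriched list, led by miR-126a-3p (339 ± 69.1 CPM in HFD and 539 ± 197 CPM in NCD islets), had 3 of 3 negative and an adjusted p of 0.0688. Its other members, miR-126a-5p and miR-126b-3p, hold the same reads. The liver and muscle markers had 3 of 4 negative and an adjusted p of 0.0688, with miR-122-5p and miR-206-3p, both raised in NCD 1, called when adjusted over the list alone. Of the 6 leukocyte-enriched miRNAs, 5 had negative fold changes and miR-146a-5p was the exception and the 1 call when adjusted over the list alone (camera adjusted p = 0.602, and 0.0640 without miR-146a-5p). The erythroid list (adjusted p = 0.48), the fibroblast and smooth muscle list (0.48), the adipose list (0.634) and the epithelial miR-200 family (0.48) had 0 calls.

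Among the other families and clusters, the miR-17/92 clusters had 8 of 10 members with negative fold changes, a median of -0.59 and a camera adjusted p of 0.0688. miR-92a-3p was at 74.6 ± 22.7 CPM in HFD and 140 ± 38.1 CPM in NCD islets. All tested members but miR-25-3p (-1.09) were higher in NCD 3 than in the mean of the other libraries on the log2 scale, from 0.37 for miR-106b-3p to 1.49 for miR-17-5p. The last is named here outside the naming rule, as the end of this range. The Dlk1-Dio3 imprinted cluster had 45 of 72 positive, a median of 0.08 and an adjusted p of 0.193. The miR-181 family had an adjusted p of 0.353. The miR-15/16, miR-29, let-7, Sfmbt2, miR-30 and miR-34 lists, the list of miR-26 and miR-101, that of miR-183, miR-96 and miR-182, and that of miR-221 and miR-222 had adjusted p from 0.48 to 0.798. Over these lists 0 members were called when adjusted over the list alone. The list of miR-103 and miR-107 and the miR-33 and miR-122 list had fewer than 3 tested members and no list test, and the 1 tested member of the latter was miR-122-5p. With an estimated correlation each list's adjusted p was 0.671 or more. Leaving out a library raised the number of lists past the threshold to 4 (HFD 1), 7 (HFD 2), 1 (HFD 3), 3 (NCD 2) or 6 (NCD 3), and leaving out NCD 1 kept it at 0.

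**Figure D3:**
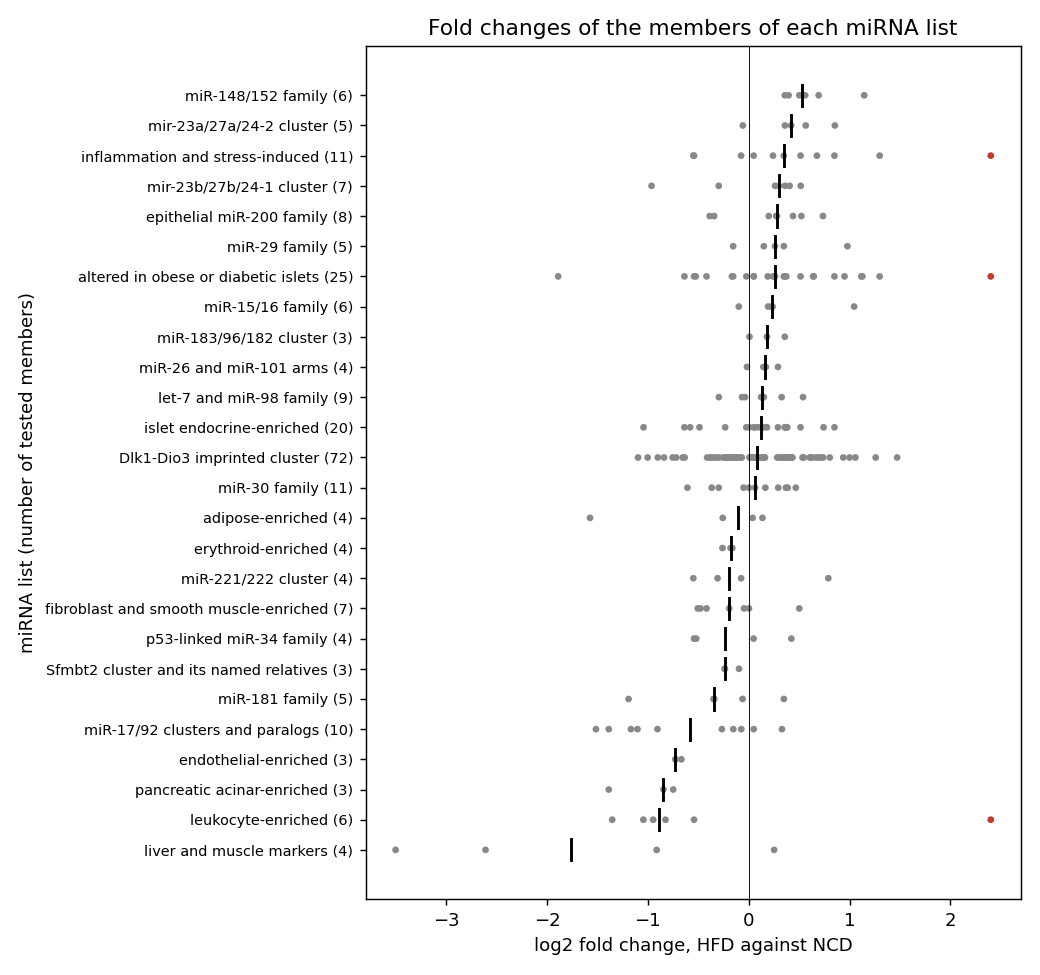
Log2 fold changes in HFD against NCD islets of the tested members of each of the 26 lists (number of members in parentheses), with a black bar at each list's median. The red points are all miR-146a-5p, which 3 lists hold, and the miR-148 and miR-152 family is the list with the highest median, at 0.53.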

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

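Tests on reverse-complementary rows, on GC trends and on lists without miR-146a-5p were chosen after the data were seen. The count of called miRNAs was 1 at first. It was 0 with library totals only, 8 without a filter, 3 with DESeq2 and 0 with limma-trend at either pseudocount. It ran from 0 to 4 when 1 library was left out, counting miR-122-5p and miR-122b-3p separately, and miR-146a-5p was called under 19 of 23 alternatives. The cause of these shifts was not tested.

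The fold change of miR-27a-5p was positive under each of its 22 alternatives, from 0.44 to 0.96 on the log2 scale, with adjusted p from 0.321 to 0.87. The number of lists past the threshold, 0 at first, was 2 with library totals only, 5 without a filter, 1 with a mean of at least 100 counts, 1 without the most abundant miRNA, 1 with 1 row per reverse-complementary pair and 1 without miR-146a-5p. It ran from 0 to 7 when 1 library was left out. The miR-148 and miR-152 family passed under 10 of 18 alternatives, the inflammation and stress-induced list and the liver and muscle markers under 6 each, the acinar-enriched list under 5 of 17 and the list altered in obese or diabetic islets under 4. With an estimated correlation 0 lists passed (lowest adjusted p = 0.671), as with fry's test for a shared direction (0.461). The robust setting and the choice of edgeR or limma-voom do not enter the camera test and were not run for lists. The arm ratio difference ran from -0.18 to 0.53 when 1 library was left out, reversing without HFD 2.

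The deviations of libraries with the same replicate number correlated at 0.18, -0.24 and 0.37 across miRNAs for numbers 1, 2 and 3, not each above 0.1, so the numbers were not taken as pairs. HFD 3 correlated best with NCD 3, the highest value of any combination, while HFD 1 correlated best with NCD 2 (0.31) and HFD 2 with NCD 1 (0.30). With the replicate block the count of called miRNAs was 1, the miR-27a-5p log2 fold change 0.83, the number of lists 4 and the arm ratio difference 0.26. With the GC trend also removed the first 2 values were 1 and 0.87.

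Of 874 values for 40 other named miRNAs, 24 changed direction, each for a fold change that had not passed. With library totals only these were miR-132-3p (-0.14), miR-24-3p (-0.069), miR-3074-5p (-0.068), let-7f-5p (-0.086), miR-200b-3p (-0.037) and miR-26a-5p (-0.17). With limma-trend they were let-7f-5p (-0.091), miR-200b-3p (-0.045) and miR-26a-5p (-0.20) at either pseudocount. miR-375-3p turned to 0.054 with limma-voom, 0.058 with the block, and 0.095 with the block and GC trend removed. When 1 library was left out, miR-375-3p ran from -0.37 to 0.22, let-7f-5p from -0.17 to 0.50, miR-26a-5p from -0.11 to 0.29, miR-23a-3p from -0.24 to 0.060, miR-342-3p from -1.45 to 0.13 and miR-142a-5p from -1.43 to 0.17. Depth limits rare miRNAs, since a count of 0 allows up to 0.445 CPM in the shallowest library.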

Other observations

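The tests on leukocytes, on miR-146b-5p, on muscle and on liver were chosen only after the results they bear on had been seen, as were the miRNAs named here that the naming rule does not give (miR-133a-3p, miR-192-5p, miR-194-5p, miR-802-5p, miR-122-3p, miR-142a-3p and miR-223-3p). The fry test for change in either direction passed for 4 lists: leukocyte-enriched (adjusted p = 0.0187), inflammation and stress-induced (0.0347), mir-23b/27b/24-1 cluster (0.0388) and altered in obese or diabetic islets (0.0392). The list of the cluster does not hold miR-146a-5p and the other 3 do. Without miR-146a-5p among the miRNAs, the values were 0.706, 0.196, 0.108 and 0.265. Each value is adjusted over the lists, so that of the cluster also moves with the p-values of the other lists. Its unadjusted p in fry's test for either direction was 0.00447 with miR-146a-5p included. The rise to 0.108 therefore does not show that the cluster's own values depend on miR-146a-5p. NCD 1 also held the highest levels of the blood cell miRNAs miR-142a-3p (4.30 CPM) and miR-223-3p (5.78 CPM), against means of 0.884 and 0.985 CPM in the other 5 libraries. These levels rest on 29 and 39 reads in NCD 1. The summed level of the tested leukocyte-enriched miRNAs other than miR-146a-5p was instead highest in NCD 3, with 90.1 CPM against 42.7 CPM in NCD 1.

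The real split of the 6 libraries called 1 miRNA and the highest of the other splits 0, so 1 of 10 splits gave as many. For lists the real split gave 0, so all 10 splits had to give as many or more, and this count could not decide. The highest other split, of HFD 1, HFD 3 and NCD 3 against the rest, gave 6. With 10 splits no share under 0.05 can be reached. The list test assumed a correlation of 0.01 between members, while the estimated correlation was 0.98 for the erythroid, 0.97 for the acinar and 0.75 for the endothelial list. Some rows of these lists appear to hold the same reads, as do miR-486a-5p, miR-486a-3p and miR-486b-3p (639, 661 and 637 reads) in the erythroid and miR-126a-5p and miR-126b-3p (664 each) in the endothelial list. Whether correlated members or another structure of the samples gives the calls of arbitrary splits was not tested.

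For the higher miR-146a-5p in HFD islets, 3 explanations were tested. Leukocytes in the HFD samples would raise the 5 other tested leukocyte-enriched miRNAs. Their summed level was 27.9 ± 4.03 CPM in HFD and 54.5 ± 31.4 CPM in NCD islets, a difference of -26.6 CPM. The rise in miR-146a-5p was 3282 CPM. The fold changes of these 5 were known to be negative before the test was chosen, so the sum restates them and is not separate evidence. NCD 3 held 90.1 CPM of the sum, and without it the difference was -8.81 CPM. Reads moved from miR-146b-5p would lower that row and leave the sum of both unchanged. The row of miR-146b-5p was not lower, with a log2 fold change of 0.68 ± 0.34 (SE). The summed counts had a log2 fold change of 2.12 ± 0.34 (SE). Since both rows were already known to be higher in HFD islets, the sum had to be higher too and is not separate evidence. With the GC trend of each library removed the log2 fold change was 2.35, against 2.40 before, and the edgeR adjusted p was 0.00276. The linear GC trends of these libraries therefore did not account for the rise. They were too weak to move a fold change of this size, so this test could not decide on GC-dependent recovery of another form. A diet effect may remain as a hypothesis, and in which cells of the islet samples the rise lies was not tested. The small number of libraries and a difference between samples other than diet stay open.

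For library NCD 3, GC-dependent recovery was tested as the reason that it stands apart. Its deviation from the other libraries correlated with GC content across miRNAs at a Spearman rho of 0.155. The value was larger in size in HFD 1 (-0.242), HFD 2 (0.284), HFD 3 (-0.282) and NCD 2 (-0.237), and was 0.111 in NCD 1. The strength of this correlation therefore did not set NCD 3 apart. It was too far from 0 to exclude some GC-dependent recovery in NCD 3. The 53 miRNAs at least doubled there had a median GC content of 52.2% and the 45 at least halved 45.5%. The acinar-enriched miRNAs stayed higher in NCD 3 with the GC trend removed, with a median deviation of 1.88 on the log2 scale against 1.92 before. The median before was that of miR-217-5p, whose GC content of 47.8% equals the median of all tested miRNAs. A linear GC trend could hardly move it, so this test could not decide. More exocrine tissue in NCD 3 may be a candidate explanation, but it rests on 3 miRNAs and was not tested further, and no biological explanation was tested.

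For library NCD 1, tissue from outside the islets was tested for miR-206-3p and miR-122-5p. The sum of the muscle miRNAs miR-1a-3p and miR-133a-3p exceeded the mean of the other 5 libraries by 28.2 CPM, where its SD in those 5 was 21.97 CPM. This was less than the 55.6 CPM for miR-206-3p, while muscle as the cause was taken to require at least as much. The excess came from miR-1a-3p, which had 67.3 CPM in NCD 1, close to the 63.1 CPM of NCD 2. miR-133a-3p was not raised in NCD 1, with 1.04 CPM against a mean of 1.23 CPM in the others, but had only 7 reads. Levels of different miRNAs are also hard to compare, so skeletal muscle stays open. Of 4 other liver miRNAs, 3 (miR-192-5p, miR-194-5p and miR-122-3p) were highest in NCD 1 and miR-802-5p was not, so liver tissue may have contributed but could not be settled. The levels of miR-192-5p were 905 CPM in NCD 1 and 507 CPM on average in the others, miR-122-3p had 8, 8 and 9 reads in NCD 1, 2 and 3, so that its rank comes from the scaling, and no biological explanation was tested for miR-206-3p or miR-122-5p.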
